A study of Mus musculus with 2 samples.

How the data were processed

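Single-cell RNA sequencing was performed on cells of the mouse small intestine (strain C57BL/6J) from 2 libraries, 1 per genotype. The WT library came from mice with an intact Gabbr1 gene, and the KO library from mice in which a floxed Gabbr1 allele is deleted by Cre recombinase expressed from Rorc. Mice of both genotypes received 2.5% dextran sulfate sodium (DSS), a detergent-like polysaccharide that injures the intestinal epithelium, so no untreated tissue was compared here. Per the labels, leukocytes positive for CD45 and CD127, and CD45-negative cells positive for EpCAM, were sorted by flow cytometry and mixed in equal parts before loading. The number of mice behind each library is not given in the sources used here. The library protocol in the labels names the Singleron GEXSCOPE kit, whereas a description field names 10x Genomics; the deposited barcodes consist of 3 segments of 9 bases. Per the submitters' processing notes, which list names without roles or order, FastQC, fastp, cutadapt, STAR, featureCounts, R 4.2.2 and Seurat 4.3.0 were used with the mm10 build.

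The authors deposited 1 table per library with 1 line per cell, and no values per gene were analysed here. Per the file headers, each line gives the total count of the cell (read here as unique molecular identifiers, UMIs), the number of genes detected, the percent of counts from mitochondrial genes, a Seurat cluster number from 0 to 22, and the authors' annotation at a coarse level (Immune, Epithelial or Others) and at a fine level of 23 classes. The deposited counts per cell are whole numbers without normalization, and the lowest was 500 in both libraries. The deposited mitochondrial percent values stayed below 15.0 and the lowest gene numbers were 203 in WT and 201 in KO, so cells outside such limits are not in the tables. How the classes were assigned and whether doublets were removed is not given in the sources used here. A doublet caller needs counts per gene and was not run; leaving out the 1% of cells with the most UMIs in each library served as a partial check for epithelial cells only, since it removed 0 immune cells.

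From these tables, the share of each class was computed per library with its exact Clopper-Pearson 95% binomial interval. The sort and the mixing set part of the balance between compartments. The denominator was therefore the immune cells for the 13 immune classes and the epithelial cells for the 7 epithelial classes. The 3 classes under Others are annotated as neither Immune nor Epithelial and were taken as shares of all cells. The KO to WT ratio of shares was formed as a description, with the range of ratios that the bounds of both intervals allow. Intervals cover counting error only. With 1 library per genotype there is no replicate error, so no test was made and no p-value is given; a difference between the libraries can be one of animals, dissociation or sorting as well as of genotype. Depth, genes per cell and mitochondrial percentage were summarised as medians and quartiles over cells, and cells were not treated as replicates. Genes per cell could not be thinned to a common depth, and were compared within 10 bins of UMI count.

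The rule for the classes to lead with was fixed before the data were examined. A class qualified with at least 20 cells over both libraries, a ratio of at least 1.5 or at most 0.667, and intervals that do not overlap. "The rule" below means this one. Alternatives fixed at the same time were all cells as denominator, a mitochondrial percentage of at most 10, at least 1000 UMIs, at least 500 genes, leaving out the 1% of cells with the most UMIs, equal weight for each decile of UMI count in the compartment, leaving the most abundant class out, and, for depth, means and class medians. Leaving out cluster 3, leaving out the class labelled proliferating TC, a mitochondrial percentage of at most 5, and WT cluster weights were added after seeing the data. The planned gene lists and expression comparisons, including the level of Gabbr1 as a check of the labels, were not analysed here because the tables hold no values per gene. Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10.

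The script was tested on simulated data made from the WT shares of the 13 immune classes, with 200 simulated library pairs. The exact intervals held the true share in 95.3% of cases. Classes with a true ratio over 1.8 or under its inverse qualified under the rule in 99.3% of cases, and classes with a true ratio within 1.2 in 0.312%. Cells were drawn from fixed shares, without a spread between animals, sorts or dissociations. These rates therefore hold for counting error only. A separate simulation used invented UMI counts, with the KO library shallower throughout. There, for a class whose share depended on depth alone, the ratio was 0.776 without and 0.988 with UMI deciles weighted equally. A depth gap that differs between classes, as in the real libraries, was not simulated. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.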

Results

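Single-cell RNA sequencing of the small intestine of DSS-treated mice gave 30343 annotated cells, whose class shares and quality measures were compared between genotypes in 1 library of 14998 cells from mice with intact Gabbr1 (WT) and 1 of 15345 cells from mice lacking it in Rorc-expressing cells and their progeny (KO). Gabbr1 (ENSMUSG00000024462.17, protein-coding, GRCm38 chromosome 17, 37045966 to 37075067, plus strand) encodes a subunit of the metabotropic GABA-B receptor. Rorc (ENSMUSG00000028150.14, protein-coding, chromosome 3, 94372794 to 94398276, plus strand), whose regulatory sequences drive the Cre, encodes the transcription factor RORγt of group 3 innate lymphoid cells (ILC3) and Th17 cells, and is also expressed by developing T cells in the thymus. The level of Gabbr1 was not analysed here, so the genotype rests on the labels. The WT library held 74164453 UMIs with a median of 1923 per cell, and the KO library 66948807 UMIs with a median of 2002 per cell. The sort took immune cells carrying CD127, the interleukin-7 receptor alpha chain found on innate lymphoid cells and many T cells, and epithelial cells carrying EpCAM. Shares of immune cells are therefore shares of the sorted cells and also depend on how each sort was gated. Annotated immune cells made up 60.7% of the WT library (exact 95% binomial interval 59.9 to 61.4) and 61.6% of the KO library (60.8 to 62.4). Epithelial cells made up 38.0% (37.3 to 38.8) and 35.2% (34.4 to 35.9). Both populations were mixed in equal parts, so these balances depart from the mix, and the cause was not tested. Because the sort and the mixing also set them in part, shares below are given within each compartment. All intervals are of this kind and cover counting error only; no spread between animals can be had from 1 library per genotype.

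The first comparison concerned innate lymphoid cells, whose ILC3 group is known to express Rorc. ILC3 formed 28.3% of WT immune cells (27.4 to 29.2) and 14.7% of KO immune cells (13.9 to 15.4), a ratio of 0.518. All 3 annotated ILC3 classes were lower in KO. The CCR6 class, which corresponds to lymphoid-tissue-inducer-like cells, stood at 12.9% (12.2 to 13.6) in WT and 6.21% (5.73 to 6.72) in KO, a ratio of 0.483. The Ncr1 class, named after the gene of the natural cytotoxicity receptor NKp46, stood at 10.5% (9.90 to 11.2) and 5.86% (5.40 to 6.36), a ratio of 0.557. The class labelled DN ILC3 stood at 4.91% (4.48 to 5.38) and 2.58% (2.27 to 2.92), a ratio of 0.526. ILC1, the interferon-gamma-producing group, was also lower, at 3.37% (3.01 to 3.77) against 1.90% (1.64 to 2.20), a ratio of 0.564. ILC2, the group that makes type 2 cytokines, differed less, with 19.3% (18.5 to 20.1) in WT and 16.5% (15.8 to 17.3) in KO. Its ratio of 0.857 lay outside the rule although the intervals did not overlap, and it was 1.04 with Th2 cells left out of the denominator. Altogether 51.0% of WT immune cells and 33.1% of KO immune cells were innate lymphoid.

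Within the innate lymphoid cells, ILC3 accounted for 55.5% in WT (54.1 to 56.9) and 44.3% in KO (42.5 to 46.0), and ILC2 for 37.9% (36.5 to 39.3) and 49.97% (48.2 to 51.7). ILC1 held 6.62% (5.92 to 7.37) and 5.75% (4.96 to 6.63), with overlapping intervals. In the makeup of the ILC3 group itself, the intervals of each class overlapped between the libraries, which does not show that the shares are equal. The CCR6 class formed 45.5% of ILC3 in WT (43.5 to 47.4) and 42.4% in KO (39.8 to 45.0). The Ncr1 class formed 37.2% (35.3 to 39.1) and 40.0% (37.4 to 42.6), and the DN class 17.4% (15.9 to 18.9) and 17.6% (15.6 to 19.7). The median UMI count of ILC3 was 1574 in WT and 1906 in KO, so the smaller ILC3 share was found in the library with the deeper ILC3 profiles. With Th2 cells left out of the denominator, the ratio of Ncr1 ILC3 was 0.675 and that of ILC1 0.684, both outside the rule. With UMI deciles weighted equally, the ratio of ILC1 was 0.681.

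**Figure D1:**
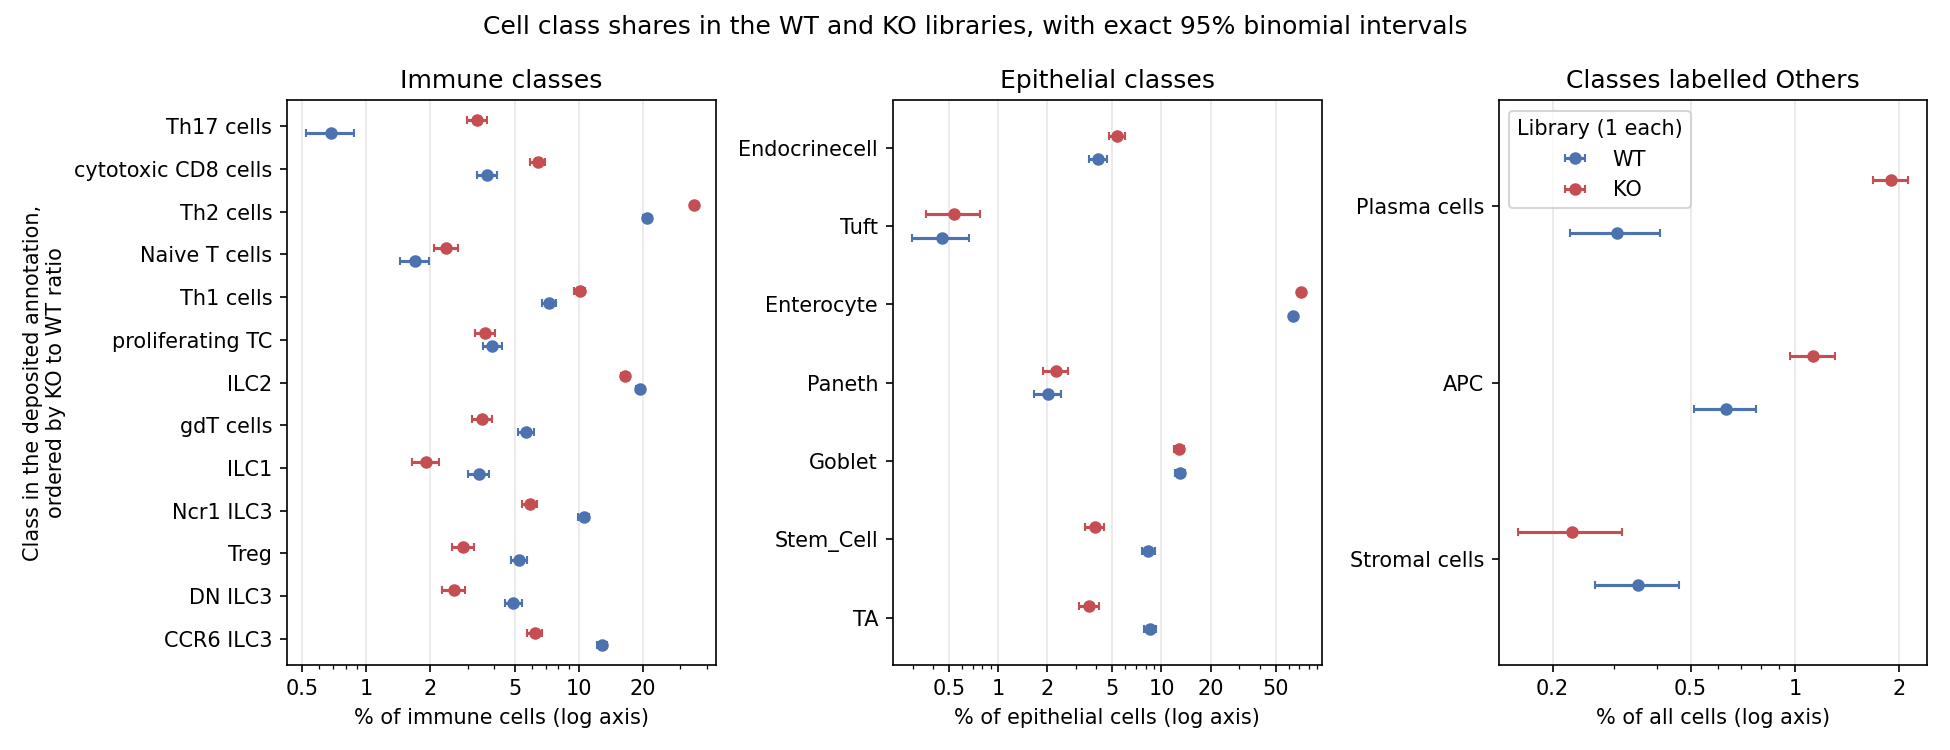
Share of each annotated class (horizontal log axes, percent of the immune, epithelial or all cells) in the WT and KO libraries, 1 library each, with points for the share and bars for the exact 95% binomial interval. Among immune classes, Th17 cells have the highest ratio (4.88) and CCR6 ILC3 the lowest (0.483), and among epithelial classes TA (0.424) and Stem_Cell (0.470) are the lowest.

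The second comparison concerned the remaining immune classes, nearly all named as T cells, which together formed 49.0% of WT immune cells (48.0 to 50.1) and 66.9% of KO immune cells (65.9 to 67.8). Th17 cells, the helper T cells that depend on RORγt, were 0.681% in WT (0.523 to 0.873; 62 cells) and 3.32% in KO (2.97 to 3.70; 314 cells). Their ratio of 4.88 was the highest of the 13 immune classes, and the interval bounds put it between 3.40 and 7.08. Th2 cells, the helper cells of type 2 responses and the most abundant immune class, were 20.9% (20.1 to 21.8) in WT and 34.7% (33.8 to 35.7) in KO, a ratio of 1.66. With UMI deciles weighted equally it was 1.58, with Th2 cells higher in KO in 8 of 10 deciles and lower in 2, among them the topmost (0.610). Cytotoxic CD8 cells were 3.72% (3.34 to 4.12) and 6.39% (5.91 to 6.90), a ratio of 1.72.

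Regulatory T cells (Treg), which restrain immune responses, were lower in KO, at 5.23% (4.78 to 5.71) against 2.86% (2.53 to 3.21), a ratio of 0.546. Gamma delta T cells were also lower, at 5.63% (5.16 to 6.12) against 3.51% (3.15 to 3.90), a ratio of 0.624. Th1 cells were 7.23% (6.71 to 7.78) in WT and 10.1% (9.48 to 10.7) in KO, a ratio of 1.39, and naive T cells were 1.69% (1.44 to 1.98) and 2.38% (2.08 to 2.71), a ratio of 1.41. Both lay outside the rule, with intervals that did not overlap; with at least 1000 UMIs the ratios were 1.56 and 1.61, past the rule. The class labelled proliferating TC was 3.92% (3.53 to 4.34) and 3.62% (3.25 to 4.02), with overlapping intervals and ratios from 0.695 to 1.12 over the alternatives. In all, 3 immune classes were higher in KO by the rule, 6 were lower and 4 did not qualify.

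Taken as shares of the immune classes other than innate lymphoid cells, Th17 cells were 1.39% in WT (1.07 to 1.78) and 4.97% in KO (4.44 to 5.53). Treg were 10.7% (9.78 to 11.6) and 4.27% (3.79 to 4.80), and gamma delta T cells 11.5% (10.6 to 12.4) and 5.25% (4.71 to 5.83). On this denominator these 3 classes passed the rule, while the ratio was 1.22 for Th2 cells, 1.26 for cytotoxic CD8 cells, 1.02 for Th1 cells and 1.03 for naive T cells. Proliferating TC were 8.003% (7.22 to 8.84) and 5.41% (4.86 to 6.00) on this denominator, a ratio of 0.676 just outside the rule with intervals that did not overlap, and 0.611 and past it with at least 1000 UMIs. Of the annotated Th17 cells, 358 of 376 lay in cluster 0, which Th2 cells dominate. Within that cluster the Th17 share was 2.68% in WT (2.03 to 3.45) and 7.96% in KO (7.11 to 8.87). The size of the Treg difference varied with the filter on depth. The median Treg cell had 1135 UMIs in WT and 1588 in KO. Among cells with at least 1000 UMIs the ratio was 0.711 over all immune cells, outside the rule, and 0.516 over the immune classes other than innate lymphoid cells, past it. Equal weights for UMI deciles left the ratio at 0.716 for Treg, 0.693 for gamma delta T cells and 1.46 for cytotoxic CD8 cells, which fall short of 1.5-fold, and at 1.66 for Th1 cells and 1.81 for naive T cells, which exceed it. Without Th2 cells in the denominator the ratio of gamma delta T cells was 0.756.

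The third comparison concerned the epithelium, which lies outside the lymphoid lineages known to express Rorc. Stem_Cell, the class of crypt-base stem cells, made up 8.32% of WT epithelial cells (7.62 to 9.07; 475 cells) and 3.91% of KO epithelial cells (3.41 to 4.46; 211 cells), a ratio of 0.470. The class labelled TA, an abbreviation that in this tissue usually denotes transit-amplifying progenitors, made up 8.48% (7.77 to 9.24) and 3.59% (3.11 to 4.13), a ratio of 0.424. Enterocytes, the absorptive cells, were the most abundant class, with 63.6% in WT (62.3 to 64.8) and 71.5% in KO (70.3 to 72.7), a ratio of 1.12. Over the alternatives the enterocyte ratio ran from 1.04, over all cells, to 1.13. It was 1.06 both with at most 10% mitochondrial counts and without cluster 3, a cluster of low depth. Stem_Cell and TA passed the rule as lower in KO and no epithelial class passed it as higher.

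The secretory classes lay closer together. Mucus-producing goblet cells were 13.04% (12.2 to 13.9) and 12.9% (11.98 to 13.8), and Paneth cells, which secrete antimicrobial peptides at the crypt base, 2.02% (1.67 to 2.41) and 2.26% (1.88 to 2.69). Hormone-secreting enteroendocrine cells, labelled Endocrinecell, were 4.10% (3.60 to 4.65) and 5.34% (4.75 to 5.97), with intervals that did not overlap and a ratio of 1.30. That ratio passed the rule without enterocytes in the denominator (1.66) and without cluster 3 (1.52). Tuft cells, the chemosensory class, were 0.456% (0.298 to 0.667) and 0.537% (0.360 to 0.771). The ratios of goblet, Paneth and tuft cells lay on either side of 1 over the alternatives, from 0.886 to 1.26, from 0.964 to 1.43 and from 0.819 to 1.97. Only 55 cells carried the tuft label, and 37 of them lay in cluster 3, a cluster of low depth described below. Among the TA cells, 52.9% of those in WT lay in cluster 8, the stem cell cluster, and 68.6% of those in KO in cluster 4, an enterocyte cluster.

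Cells annotated as Others, neither Immune nor Epithelial, were counted among all cells. Plasma cells, the antibody-secreting B-lineage cells, made up 0.307% of the WT library (0.225 to 0.409; 46 cells) and 1.89% of the KO library (1.68 to 2.12; 290 cells). This ratio of 6.16 was the highest of all 23 classes. The class labelled APC was 0.633% (0.513 to 0.774) and 1.13% (0.966 to 1.31), a ratio of 1.78, which was 1.498 and just outside the rule with UMI deciles weighted equally. Stromal cells were 0.353% (0.265 to 0.462) and 0.228% (0.159 to 0.317), with overlapping intervals. Through which gate these cells came is not given in the sources used here. Their shares also depend on how cleanly each sort was gated.

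Depth and mitochondrial percentage differed between the libraries in a way that depended on the cell class. Immune cells had a median of 1596 UMIs in WT (quartiles 1236 and 2100) and 1830 in KO (1473 and 2330). The median was higher in KO in 11 of the 13 immune classes, by ratios of 1.04 to 1.40, and lower in Th2 cells (1895 against 1735) and cytotoxic CD8 cells (2174 against 2123). Epithelial cells had a median of 10058 UMIs in WT (2220 and 15639) and 4976 in KO (1260 and 14365). Medians were lower in KO in enterocytes, with 11683 against 5051 UMIs, in TA cells, with 11194 against 5934, and in stem cells, with 12821 against 9648. The ratios of all epithelial cells and of enterocytes varied with the summary and the filter. The epithelial ratio of 0.495 was 0.810 as means and 1.04 with at most 5% mitochondrial counts. The enterocyte ratio of 0.432 was 0.821 as means, 1.16 with at most 5% and 1.09 with WT cluster weights, the last 2 being settings that themselves select or weight by depth. Goblet, Paneth and enteroendocrine cells had ratios of 1.02, 1.15 and 1.06. The median mitochondrial percentage of enterocytes was 4.62% in WT and 7.11% in KO, and that of TA cells 6.06% and 9.98%, while immune cells stood at 2.22% in both libraries. By class, the median was higher in KO in 6 of the 7 epithelial classes, all but Paneth cells, and in 10 of the 13 immune classes. Enterocytes with over 10% mitochondrial counts made up 14.7% of that class in WT (13.6 to 15.9) and 33.5% in KO (32.0 to 35.0).

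**Figure D2:**
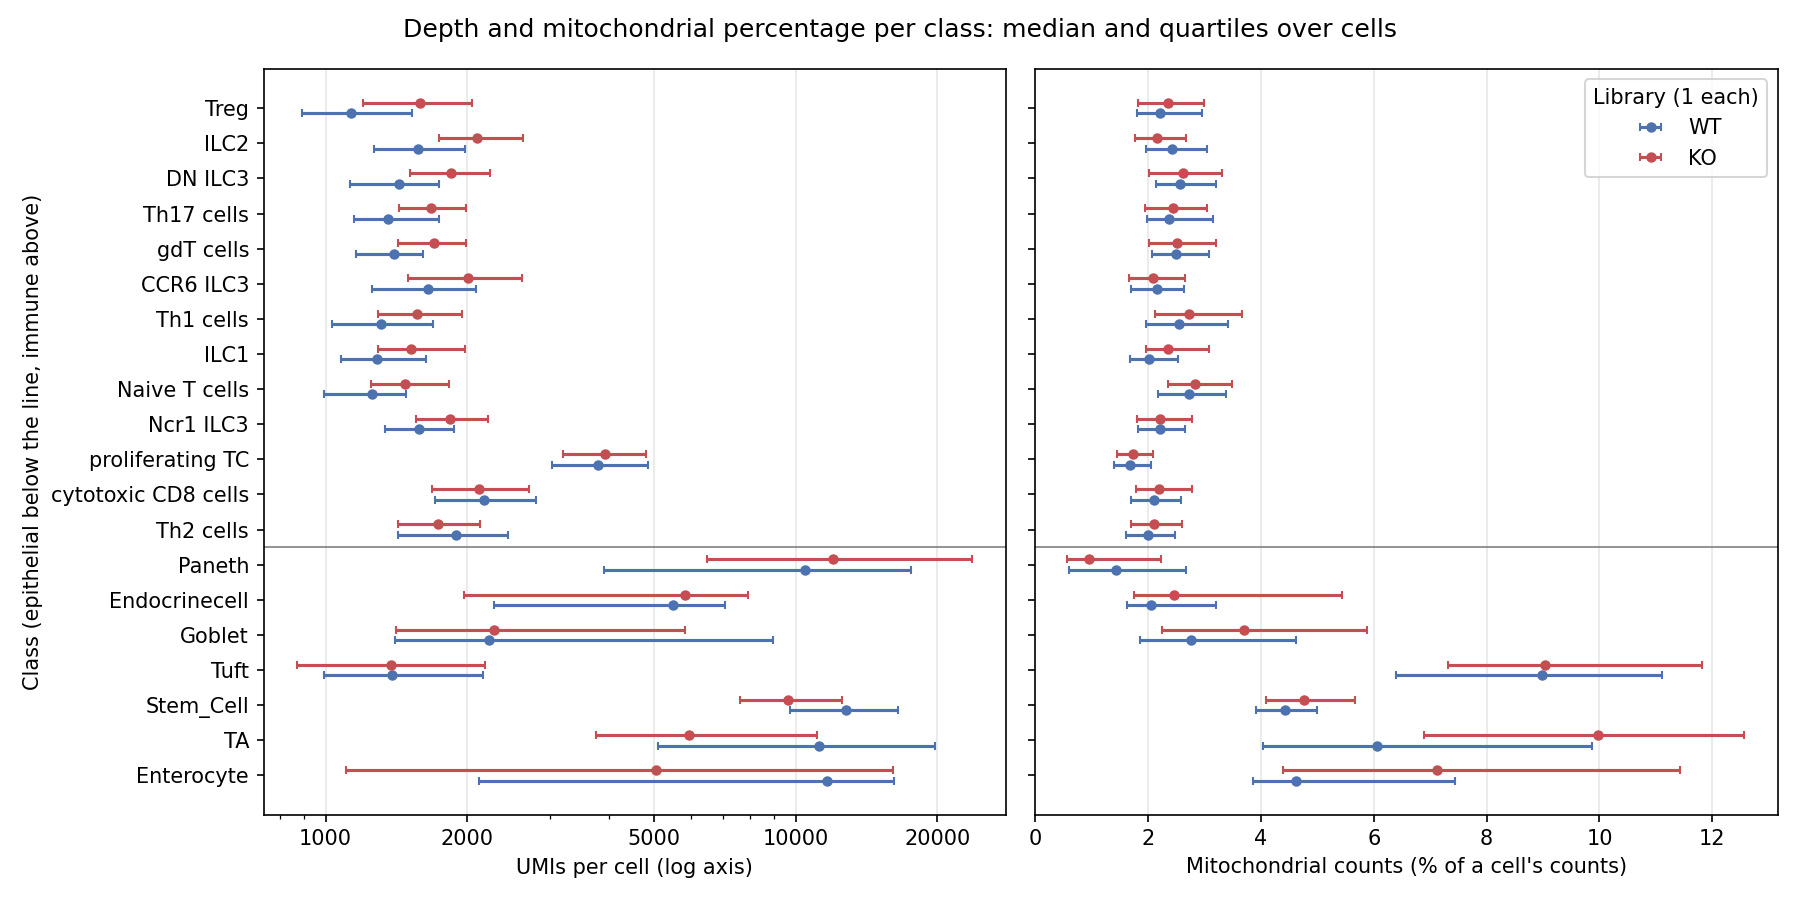
UMIs per cell (left, log axis) and mitochondrial percentage (right) of each immune and epithelial class in the WT and KO libraries, with points for the median and bars for the quartiles over cells. Medians of immune classes are mostly higher in KO, whereas enterocytes (11683 against 5051 UMIs), TA cells and stem cells have lower medians in KO; the enterocyte ratio of 0.432 is 0.821 as means, and the direction turns with at most 5% mitochondrial counts (1.16) and with WT cluster weights (1.09).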

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

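The tests of depth, cluster weights, mitochondrial percentage and cluster 3 were laid down before their results were seen; the tests on ILC2 and ILC1, cluster 1, the immune classes' depth and Paneth cells were chosen after. For cluster weights and for the limit of 5% mitochondrial counts, a ratio of 0.8 or more was first to be read as fitting; after the values were seen both tests were judged void, because clusters and limit select on depth. Differences between cell classes in this part were not tested, since each genotype has 1 library.

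Some classes went in opposite directions under the same contrast and drew attention for that. Th17 cells had a KO to WT ratio of 4.88 and ILC3 one of 0.518, although both groups are known to express Rorc; recombination was not measured in either. The median UMI count of enterocytes had a ratio of 0.432 and that of immune cells one of 1.15. The median UMI count of Th2 cells had a ratio of 0.916 and that of ILC2 one of 1.34. In the cluster numbers of the enterocytes, which the comparison of enterocyte shares did not use, cluster 3 held 38.3% of KO enterocytes (36.8 to 39.9) and 21.9% of WT enterocytes (20.6 to 23.3).

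The lower ILC3 share in KO was set against 4 technical or arithmetic explanations. A rise of the T cell classes alone would leave ILC3 in proportion to ILC2, but ILC3 were 59.4% of both together in WT (58.0 to 60.9) and 47.0% in KO (45.2 to 48.8). The depth gap is argued against as the whole cause by a ratio of 0.510 with UMI deciles weighted equally. KO was lower in 9 of 10 deciles and higher in the topmost (1.69). This weighting covers the deposited cells only, so cells lost below 500 UMIs could not be weighed. Relabelling inside clusters is argued against by the labels in cluster 1, which holds nearly all ILC3. Another label was carried by 7 of its 2578 WT cells and 10 of its 1393 KO cells. The share of cluster 1 had a ratio of 0.520, but this repeats the ILC3 ratio, because cluster and label hold nearly the same cells. Cells placed in other clusters were not tested. A rise of the T cell classes and ILC2 together stays open, since ILC3 were 89.3% of ILC3 plus ILC1 in WT and 88.5% in KO with overlapping intervals, and shares hold no absolute cell numbers. Genotype and animal or library differences other than genotype cannot be told apart with 1 library per genotype.

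The cause of the fewer UMIs per cell in KO enterocytes (ratio 0.432) was left open by the tests made. Shallower sequencing of the whole KO library is argued against by 11 immune classes with a higher median in KO. Among enterocytes with at most 5% mitochondrial counts (2126 of 3628 in WT and 1360 of 3859 in KO) the ratio was 1.16, but this filter selects on depth, with WT medians of 14752 UMIs up to the limit and 2570 above it, and above it the ratio was 0.608 (1561 UMIs in KO), so the value does not decide whether cells of high mitochondrial percentage alone are the cause. With WT cluster weights in both libraries it was 1.09, and for the same reason (WT enterocyte medians of 1064 UMIs in cluster 3, 3998 in cluster 4 and 16510 in cluster 5) this does not decide whether a shift towards cluster 3 alone is the cause. Whether the KO epithelium was more injured or only handled differently stays open, as animal or library differences other than genotype (1 library per genotype) cannot be told apart from it.

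The lower share of Stem_Cell and TA together, 16.8% in WT (15.8 to 17.8) and 7.504% in KO (6.82 to 8.24), was weighed in the same way. The lower depth of KO epithelial cells is argued against as the whole cause by a ratio of 0.521 with UMI deciles weighted equally. KO was lower in 10 of 10 deciles, and the ratio was 0.524 without the 2 deciles that held under 20 such cells. The size of the difference varied with depth, with decile ratios from 0.130 to 0.865 and 0.141 in the topmost. For Stem_Cell alone the weighted ratio was 0.631 in place of 0.470, with KO higher in 2 deciles and 3 deciles under 20 cells. The excess of cluster 3 cells is argued against as the whole cause by a ratio of 0.530 without cluster 3, against 0.446 with it. Poorer recovery of whole crypts would lower Paneth cells alike if they survive handling as Stem_Cell and TA do, which was not tested. On that assumption it is argued against, since the lowest ratio the Paneth intervals allow is 0.779. This lies above the highest for Stem_Cell plus TA (0.520). A selective loss of progenitors in handling, an effect of genotype, and animal or library differences other than genotype (1 library per genotype) stay open.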

How the results depend on the processing

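No replicate could be left out and no paired analysis was possible because each genotype has 1 library. Of 220 recomputed ratios of shares, 28 could not differ from the main value because the filter removed no cell of the denominator. Of the other 192, 161 stayed within the range the main intervals allow, 31 moved out of it and 0 of the classes past the rule reversed. This range widens as cells get fewer, so staying within it says little for rare classes. Tuft ratios of 0.819 and 1.97 both did. The ILC3 ratio lay between 0.510 and 0.628, the latter without the most abundant class (Th2 cells), and was at or below 0.667 in 8 of 8 alternatives, of which leaving out the 1% of cells with the most UMIs removed 0 immune cells and checks nothing there. CCR6 ILC3, DN ILC3, Th17, Th2, Stem_Cell, TA and plasma cells stayed past the rule in the alternatives run on their shares of the compartment (of all cells for plasma cells), judged by the ratio alone with UMI deciles weighted equally, which gives no interval. For Th2 cells, leaving out the most abundant class could not be run. Among the immune classes other than innate lymphoid cells the Th2 ratio was outside the rule, at 1.22, and at 1.14 with at least 1000 UMIs. The direction was not the same in every UMI decile: Th2 cells were lower in KO in 2 of 10, DN ILC3 and gamma delta T cells higher in 3, and Treg and stem cells higher in 2. CCR6 ILC3, Ncr1 ILC3 and ILC1 were higher in KO in 1 decile each. APC were lower in KO in 3 deciles and plasma cells in 1, though 7 of 10 deciles held under 20 cells of either class. Without the deciles that held under 20 such cells the weighted ratio of gamma delta T cells was 0.662 in place of 0.693, and that of APC 1.59 in place of 1.498. The ratio of Stem_Cell plus TA was 0.521 with UMI deciles weighted equally, 0.571 without enterocytes and 0.530 without cluster 3. Immune classes higher by the rule numbered 3, and 5 with at least 1000 UMIs, where Th1 (1.56) and naive T cells (1.61) joined. Immune classes lower by the rule numbered 6, and 3 both with UMI deciles weighted equally and without Th2 cells. Epithelial classes higher by the rule numbered 0, and 1 (Endocrinecell) without enterocytes or without cluster 3. The compartment ratios were 1.02 for immune and 0.924 for epithelial cells, 1.07 and 0.808 with at most 10% mitochondrial counts, and 1.07 and 0.833 with at least 1000 UMIs. The epithelial UMI ratio of 0.495 was 0.810 as means and 1.04 with at most 5% mitochondrial counts, and the gene ratio of 0.647 was 0.990 over class medians and 0.988 with at most 5%. The enterocyte UMI ratio of 0.432 was 0.821 as means, 1.16 with at most 5% and 1.09 with WT cluster weights. The immune mitochondrial ratio of 0.998 was 1.06 over class medians and 1.02 as means. The cause of these shifts was not tested beyond the settings themselves. Tuft, plasma and stromal cells rest on few cells.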

Other observations

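Treg and Th17 cells, which share transforming growth factor beta as an inducing signal, stood in a different balance in the 2 libraries. Treg made up 88.5% of Treg plus Th17 cells in WT (85.5 to 91.0) and 46.2% in KO (42.1 to 50.4). Both classes were counted among cells sorted for CD127, so this balance also depends on how each sort was gated. Among Th17 cells and ILC3 together, Th17 cells were 2.35% in WT (1.81 to 3.01) and 18.5% in KO (16.7 to 20.4). In the epithelium, Paneth cells were 19.5% of Paneth plus stem cells in WT (16.4 to 22.9) and 36.6% in KO (31.5 to 42.1). The 4 secretory classes together were 19.6% (18.6 to 20.7) and 20.99% (19.9 to 22.1) of epithelial cells, with overlapping intervals. Enterocytes of the deep clusters 5, 6 and 16 had slightly more UMIs per cell in KO, with ratios of 1.11, 1.08 and 1.13, while their shares of the enterocytes were lower in KO, with ratios of 0.824, 0.648 and 0.595. Those of cluster 8 (109 cells in WT and 43 in KO) had fewer, with medians of 12512 and 8344 UMIs (0.667) and a ratio of shares of 0.371.

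At matched UMI counts in the 11 classes compared, enterocytes, Th2 cells and ILC2 had fewer genes per cell in KO in 10 of 10 bins, with median ratios of 0.969, 0.975 and 0.968. Th1 cells had more in 0 of 10 bins (0.968), cytotoxic CD8 cells and Ncr1 ILC3 in 2 (0.980 and 0.997), and stem, TA and goblet cells in 4 (0.990, 0.987 and 0.995). CCR6 ILC3 had more in 5 of 10 bins (1.00) and enteroendocrine cells in 5 of 10 (1.00).

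The 2 libraries shared 140 barcodes, against 133 expected by chance from the segments in use (exact Poisson interval of the observed number 118 to 165), and 23 of the shared barcodes carried the same fine label in both, against 16.1 expected.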
